A study of Mus musculus with 12 samples.

How the data were processed

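RNA was sequenced from tumour organoids of Apc min/+ mice (Mus musculus) with floxed Psen1 (called wild type, as in the labels) or with Psen1 deleted in the intestinal epithelium (called knockout), each kept for 72 h with or without EGF (50 ng/mL). Tumour cells were freed with collagenase and Dispase and grown in Matrigel, and libraries were made with an NEBNext Ultra RNA kit from column-purified total RNA, per the labels' protocols. Group and number of the 12 libraries (4 groups of 3) were taken from the labels.

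The deposited table holds raw read counts of 55536 Ensembl genes in 12 columns, 1 per library. Reads were aligned with STAR to GRCm38 (mm10) and counted with featureCounts, per the submitters' processing notes, which give no version, annotation release, strand setting or filter. Because the strand setting is not given, counts of genes that overlap another gene are uncertain. All 55536 gene IDs were found in GENCODE release M21, which gave the symbols and the GRCm38 coordinates.

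Before averaging, replicates were compared for libraries deposited more than once. Pearson correlations of log2 CPM between replicates lay between 0.9954 and 0.9972, and chi-square per degree of freedom between 5.879 and 19.37, so each library counted as a separate replicate. Depth was 39392913 to 49688129 counts per library, with 14315 to 15194 genes at 10 or more counts, and the most abundant gene, Eef1a1, took 1.2 to 1.71% of the counts. The biological coefficient of variation over all genes was 7.4%.

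Of 28171 genes with a total above 0, 15819 passed edgeR's filterByExpr by group and were tested, and these held 99.96% of the counts. Counts were normalized by TMM and fitted with edgeR 4.0.16 (robust quasi-likelihood, 1 mean per group over all 12 libraries; R 4.3.3). There were 5 comparisons: the knockout effect without EGF and with EGF, the EGF effect in wild type and in knockout, and their interaction, all by two-sided quasi-likelihood F tests with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. CPM are TMM-scaled, levels are mean ± SD over 3 libraries, and log2 fold changes are given with the SE taken from the fitted value and its F statistic. For a gene with 0 counts in all 3 libraries of a group, the fold is given as a lower bound that sets a floor of 3 counts over the group. For 1 to 3 counts it is given as a ratio with a 95% counting interval.

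Genes are named by a rule written before the data were examined. Psen1, Psen2, Egfr, Egf and Ptgs2 are always named. Per comparison, genes that passed with a mean log2 CPM of at least 1 over all 12 libraries were eligible. The 10 in each direction (5 for the interaction) with the largest log2 fold change are named. All 3 libraries of 1 group had to lie above all 3 of the other, which was not asked of the interaction. Gene models without a gene name were left out. Within a list, up to 4 members that passed are named, largest change first.

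The 30 gene lists were also written before the data were examined. Lists of signalling were the gamma-secretase complex, Notch targets, Notch receptors and ligands, the EGF receptor family and ligands, ERK pathway output, the prostaglandin pathway and Wnt targets. Lists of the epithelium were stem cells, fetal-like and regenerative epithelium, goblet, Paneth, enteroendocrine and tuft cells, enterocytes, and small-intestine and colon position. Lists of processes were cell cycle, cholesterol synthesis, glycolysis and hypoxia, the interferon response, NF-kB and inflammation, antigen presentation class II, the integrated stress and unfolded protein response, p53 targets, lysosome, and xenobiotic and antioxidant genes. The last lists were fibroblasts, endothelial cells, immune cells and mitochondrially encoded transcripts. Each was tested in each comparison with camera (limma 3.58.1; two-sided, preset correlation of 0.01 between genes), 150 tests in all, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of members that passed are given over all genes and with p adjusted over the list alone.

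Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, RLE size factors, no filter on low counts and the replicate number as a block. Others were a fit of only the 6 libraries compared, leaving out each library in turn, camera with an estimated correlation, and fry. Camera with RLE size factors, without the genes of chromosomes 10 and 19, or leaving out each library was added after the data were examined. Chromosome medians used genes with a mean of at least 8 CPM and windows of 25 neighbouring genes.

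The scripts were tested on simulated counts with 50 genes changed per fold size. For the knockout effect without EGF (15395 genes tested) the fit recovered 42, 58, 76 and 80% of genes changed 1.25-, 1.5-, 2- and 4-fold, with 9 false among 137 calls. With EGF (15341 genes) it recovered 42, 40, 74 and 74%, with 7 false of 122. For the EGF effect in wild type (15378 genes) it recovered 40, 72, 58 and 74%, with 7 false of 129, and in knockout (15392 genes) 36, 68, 76 and 92%, with 9 false of 145. For the interaction (15380 genes) it recovered 10, 48, 58 and 82%, with 6 false of 105. In the simulated list test the changed list was found, and 0 of 29 unchanged lists were called. Simulated genes varied independently, so camera on lists whose genes vary together was not tested. Cholesterol synthesis had an estimated correlation of 0.833 in the knockout effect without EGF. Few genes were changed, so normalization and recovery where most genes differ were not tested. With 1 count per gene, isoforms and exon use were not analysed.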

Results

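Gene-level read counts were measured by RNA sequencing in 12 libraries of mouse tumour organoids, cultures of tumour epithelium in a basement membrane gel. The tumours came from Apc min/+ mice, which carry a truncating Apc allele and develop intestinal adenomas. Organoids had floxed Psen1 (wild type in the labels) or lacked Psen1 in intestinal epithelial cells (knockout). Each genotype was kept for 72 h with or without epidermal growth factor (EGF, 50 ng/mL), which gave 4 groups of 3 libraries, numbered 1 to 3 within each group. Libraries 1 to 3 held 40763555, 40088585 and 42864917 counts in wild type without EGF and 49688129, 45198761 and 48176653 with EGF. In knockout they held 39392913, 41081142 and 48288423 counts without EGF and 47824369, 47452909 and 40250726 with EGF. A first principal component that separated the genotypes held 85.9% of the variance, and the next component held 3.5%. The labels do not say that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. They name the colon in the tissue field and intestinal tumours in the growth protocol. They also list EGF in the growth medium as well as in the treatment, so the medium without EGF is known only as the labels describe it.

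Psen1 encodes the catalytic subunit of gamma-secretase, the intramembrane protease that cleaves Notch receptors and many other membrane proteins (ENSMUSG00000019969, chromosome 12, 83688152 to 83735199, GRCm38). Psen1 stood at 113, 118 and 109 CPM (counts scaled to library size) in the wild-type libraries without EGF and at 106, 107 and 109 CPM in those with EGF. In the knockout libraries Psen1 stood at 13.2, 10.0 and 11.5 CPM without EGF and at 14.1, 10.5 and 10.1 CPM with EGF. The knockout level was 9.83-fold lower without EGF and 9.23-fold lower with EGF, and each of the 6 knockout libraries lay below each of the 6 wild-type libraries. On the log2 scale the difference was −3.30 ± 0.11 (SE) without EGF and −3.21 ± 0.11 with EGF, with Benjamini-Hochberg adjusted p of 2.55e-12 and 4.16e-12 by edgeR's quasi-likelihood test. One count per gene does not show which exons the remaining Psen1 reads cover. Psen2, the paralogous presenilin (ENSMUSG00000010609, chromosome 1, 180227004 to 180263438), was higher in the knockout by 0.62 ± 0.09 without EGF and 0.32 ± 0.09 with EGF on the log2 scale.

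The title of the series names the EGF receptor and the prostaglandin synthase COX2 as the pathway under study. Egfr, the receptor for EGF (ENSMUSG00000020122, chromosome 11, 16752203 to 16918158), fell from 166 ± 3.22 CPM in wild type to 61.4 ± 3.35 CPM in knockout without EGF, a log2 fold change of −1.44 ± 0.05 (edgeR adjusted p = 2.86e-15). With EGF it stood at 122 ± 1.55 CPM in wild type and 61.4 ± 4.49 CPM in knockout, a log2 fold change of −0.99 ± 0.05 (edgeR adjusted p = 1.16e-12). Ptgs2, which encodes COX2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), stood at 40.5 ± 5.67 and 39.1 ± 3.77 CPM in wild type without and with EGF, and at 0.0724 ± 0.0856 and 0.211 ± 0.0734 CPM in knockout. Its level was thus 503-fold lower in knockout without EGF and 185-fold lower with EGF (edgeR adjusted p = 3.78e-14 and 7.68e-14). The value without EGF (log2 −8.97) rests on few knockout counts and was −10.51 without knockout library 3. Egf itself, a gene of low level in these cultures (ENSMUSG00000028017, chromosome 3, 129677565 to 129755316), was also lower in knockout, by a log2 fold change of −1.76 ± 0.39 without and −3.04 ± 0.40 with EGF (−3.65 without knockout library 1 with EGF). Added EGF lowered Egfr in wild type (−0.45 ± 0.05, edgeR adjusted p = 6.54e-06), while in knockout the log2 difference was 0.00 ± 0.05, and the interaction of genotype and EGF was 0.45 ± 0.07 (edgeR adjusted p = 7.87e-04). EGF raised Psen2 in wild type by 0.47 ± 0.09 on the log2 scale (edgeR adjusted p = 0.00175). The changes of Ptgs2 with EGF did not pass the test in either genotype (edgeR adjusted p = 0.858 in wild type and 0.305 in knockout).

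**Figure D1:**
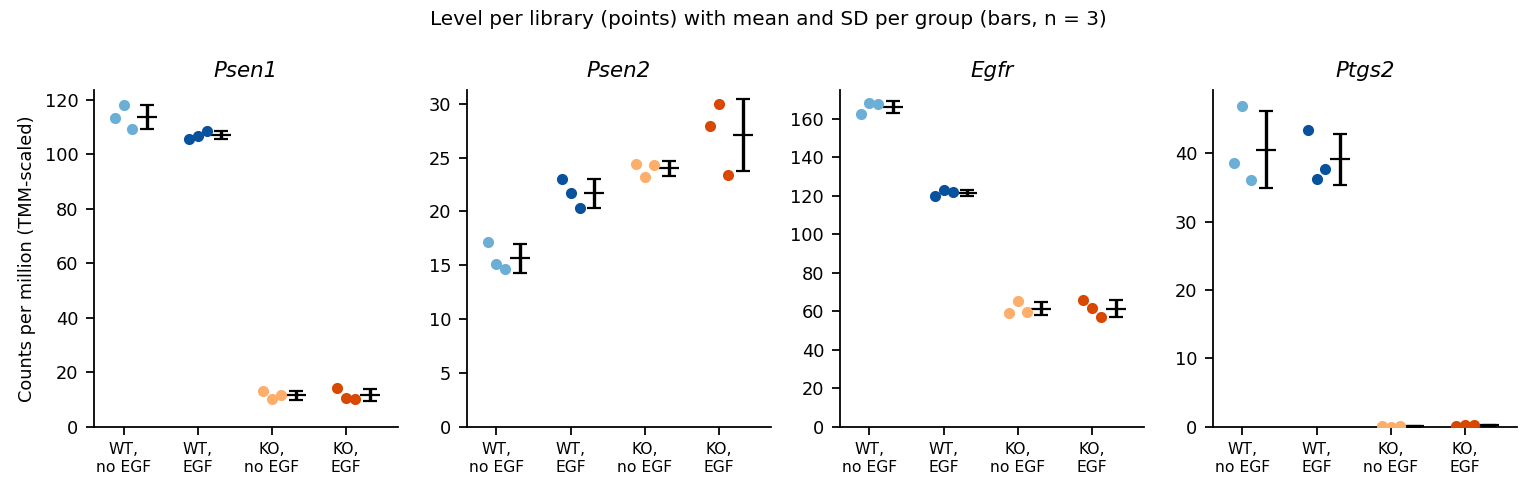
CPM per library (points) with the group mean and SD (bars) of Psen1, Psen2, Egfr and Ptgs2 in the 4 groups of 3 libraries. Psen1 lies between 10.0 and 14.1 CPM in the 6 knockout libraries, and Ptgs2 falls from a mean of 40.5 CPM in wild type to 0.0724 CPM in knockout without EGF.

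The difference between knockout and wild type, which cannot be told apart from one between organoid lines, was first read without added EGF. Genes that stood at a substantial level in one genotype and at or near 0 counts in the other led both directions. Hmga2, an oncofetal chromatin protein, was at least 1720-fold higher in knockout, Sntb1 (a syntrophin adapter) at least 1580-fold, Ppp1r9a (the actin-binding neurabin) at least 984-fold, the nucleoside transporter gene Slc28a2 at least 743-fold and Bpifa6 at least 594-fold. These bounds set 3 counts over the 3 wild-type libraries, none of which had a count, as the floor, and intervals and floors cover counting error only. Bend5 was 466-fold higher (95% counting interval 129 to 3850). Higher by log2 fold changes of 8.30 to 9.44 were Ano3 (9.44 ± 0.53), the pore-forming Gsdmc2 (9.22 ± 0.45), the amino acid transporter gene Slc6a15 (8.90 ± 0.22) and Aim2 (8.30 ± 0.16), a sensor of cytosolic DNA. In the other direction Tnfrsf11b, the decoy receptor osteoprotegerin, was at least 3720-fold lower in knockout and the serine protease inhibitor gene Serpinb7 at least 2320-fold lower. Ereg, which encodes the EGF receptor ligand epiregulin, was at least 535-fold lower, the Wnt ligand gene Wnt7a at least 492-fold, the phospholipid acyltransferase gene Lpcat2 at least 483-fold, the homeobox gene Irx5 at least 358-fold and Chic1 at least 280-fold. Slco3a1, an organic anion transporter gene, was 7310-fold lower (95% counting interval 2020 to 60400), while Wfdc2, a secreted protease inhibitor gene, and Serpinb11 changed by −12.66 ± 0.19 and −11.59 ± 0.35 on the log2 scale. Leaving out 1 library moved the fold by over 1.5 times for genes with few counts in one genotype. Without wild-type library 3, Ano3 stood at 8.85 and Aim2 at 9.25. All wild-type counts of Ano3 and Bend5 without EGF lay in library 1. Without it the group held no count, so the fitted log2 values (14.01 and 11.37) are not measured folds. Without knockout library 3, Wfdc2 stood at −12.02, Slco3a1 at −12.00 and Serpinb11 at −10.96, and without library 2 Wfdc2 stood at −13.61. All knockout counts of Slco3a1 and Serpinb11 lay in library 2, so their fitted values without it (−15.31 and −15.19) are not measured folds either. In each of these 20 genes all 3 libraries of one group lay above all 3 of the other, and the largest edgeR adjusted p was 3.32e-04, for Serpinb7.

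Across the 15819 genes tested, 10135 (64.1%) differed between knockout and wild type without EGF, 5096 higher and 5039 lower, by edgeR's quasi-likelihood test at an adjusted p under 0.05. Of these, 1581 were at least 2-fold higher and 1977 at least 2-fold lower, and the median log2 fold change of all genes was 0.01. The share of counts from mitochondrially encoded genes was 1.22 ± 0.140% in knockout and 0.950 ± 0.112% in wild type (SD). Of the 13 mitochondrially encoded genes 8 were higher in knockout, although the list as a whole did not pass the camera test (adjusted p = 0.503). Reads of near-identical copies such as those of Gsdmc2, Gsta1, Gsta2, Ly6a, Lyz1, Ces1d, Clca3a2, Cyp2a5, Saa3 and the Defa genes can be split between paralogs, so the levels of these genes are uncertain.

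Most cell cycle and cholesterol synthesis genes were higher in the knockout. All 24 cell cycle genes were higher without EGF, led by the mitotic kinase gene Aurkb (2.18 ± 0.15), the cyclin gene Ccne1 (2.16 ± 0.08), the proliferation marker Mki67 (2.00 ± 0.13) and the cyclin gene Ccnb2 (1.67 ± 0.15). The list median was 1.31 (log2), and the same 24 passed when adjusted over the list alone. Camera gave an adjusted p of 1.18e-18 (adjusted p = 0.14 with an estimated correlation). Of 23 cholesterol synthesis genes, 22 were higher, among them Acat2 (2.78 ± 0.20), the sterol sensor Insig1 (2.49 ± 0.14), Pmvk (2.47 ± 0.19) and Dhcr7 (2.34 ± 0.14). The exception was Pcsk9 (−1.60 ± 0.23), whose product degrades the LDL receptor. Pcsk9 was named here after its value was seen, as the only such member, and the same holds below for members that make up a small count. The counts adjusted over the list alone were also 22 and 1, with a camera adjusted p of 6.46e-14 (adjusted p = 0.482 with an estimated correlation). Among 19 xenobiotic and antioxidant genes 14 were higher (15 adjusted over the list alone), led by the cytochrome gene Cyp2b10 (3.28 ± 0.16), the glutathione transferase gene Gsta2 (3.13 ± 0.16), the carboxylesterase gene Ces2a (2.86 ± 0.50) and the quinone reductase gene Nqo1 (2.86 ± 0.22). Cyp3a13 (−0.92 ± 0.13) and Hmox1 (−0.31 ± 0.12) were lower. Camera tested this list at an adjusted p of 9.04e-04, and adjusted p = 0.449 with an estimated correlation.

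Most genes listed for regenerative epithelium, inflammation and the stress response were lower in the knockout. Fetal-like and regenerative genes are those of fetal gut and of repair. Of 22 tested, 15 were lower, including Ereg (at least 535-fold), Trp53i11 (−6.46 ± 0.16), the YAP target Ankrd1 (−5.93 ± 0.18) and the surface antigen Ly6a (−5.42 ± 0.09). The other direction was taken by 5 genes, namely Ly6d, Spp1, Tacstd2, Gja1 and Clu. These counts were the same adjusted over the list alone, and the call held with an estimated correlation (camera adjusted p = 4.99e-08, and 0.017 with an estimated correlation). Of 20 genes of NF-kB signalling and inflammation, 19 were lower, led by the cytokine gene Il1a (−4.81 ± 0.33), the siderophore-binding Lcn2 (−4.78 ± 0.37), the chemokine gene Cxcl3 (−4.51 ± 0.36) and Tnf (−3.73 ± 0.17). The chemokine gene Cxcl1 was higher (3.67 ± 0.36). The camera adjusted p was 1.24e-04 (adjusted p = 0.542 with an estimated correlation), and adjusted over the list alone the counts were again 19 and 1. The integrated stress and unfolded protein response list had 16 of 20 genes lower, with the transcription factor gene Atf5 (−3.41 ± 0.42), the pseudokinase gene Trib3 (−3.25 ± 0.57), Chac1 (−2.97 ± 0.51) and Atf3 (−2.72 ± 0.22) in front. Sdf2l1, Slc7a11 and Hsp90b1 were higher. For this list camera gave an adjusted p of 0.00356, and adjusted p = 0.542 with an estimated correlation. Adjusted over the list alone, 16 were lower and 3 higher. Notch receptors and ligands were lower in 7 of 8 cases, among them the ligand genes Jag1 (−1.88 ± 0.08) and Jag2 (−0.89 ± 0.06) and the receptor genes Notch4 (−1.71 ± 0.48) and Notch1 (−1.17 ± 0.11). The ligand gene Dll1 was higher (0.57 ± 0.25). The same counts passed adjusted over the list alone, with a camera adjusted p of 0.019 (adjusted p = 0.186 with an estimated correlation). DESeq2 and limma-voom each called 0 members of this list higher, so they did not share the call of Dll1.

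The lists closest to the question of the study did not pass the camera test without EGF. In the EGF receptor family Ereg (at least 535-fold), Egf (−1.76 ± 0.39), Egfr (−1.44 ± 0.05) and the ligand gene Areg (−1.34 ± 0.12) led 6 of 12 genes that were lower. Btc, Erbb3, Erbb2 and Lrig1 were higher (camera adjusted p = 0.196). ERK pathway output genes were lower in 9 of 20 cases and higher in 5 (camera adjusted p = 0.603). Etv1 (2.70 ± 0.45) and Egr1 (1.95 ± 0.15) stood at the top of this list and Spred3 (−1.68 ± 0.30) and Epha4 (−1.68 ± 0.08) at the bottom. Besides Ptgs2, the prostaglandin list had lower levels of the constitutive cyclooxygenase gene Ptgs1 (−5.37 ± 0.17) and the prostaglandin E synthase gene Ptges (−3.44 ± 0.40) and a higher level of the phospholipase gene Pla2g10 (2.24 ± 0.22). In this list 6 of 14 genes were lower and 6 higher. Its median was 0.20, its mean −0.98 and its test direction down (camera adjusted p = 0.26). Among Notch targets Notch1, Hes1 (−0.83 ± 0.06) and Notch3 (−0.43 ± 0.17) were lower of 6 tested (4 adjusted over the list alone; camera adjusted p = 0.278). In the gamma-secretase list Aph1c (−2.89 ± 0.33) and Ncstn (−0.47 ± 0.05) were lower besides Psen1, and Psen2, Aph1a and Psenen were higher. The median was 0.03, the mean −0.79 and the test direction down (camera adjusted p = 0.278). Of 17 Wnt targets 7 were lower and 5 higher (camera adjusted p = 0.619), with Notum at least 10.3-fold lower and changes of Nkd1 (2.05 ± 0.76), Tnfrsf19 (−1.64 ± 0.15) and Lgr5 (−1.39 ± 0.09). Stem cell genes were lower in 6 of 13 cases and higher in 6, led by Smoc2 (−4.82 ± 0.42), Igfbp4 (−4.58 ± 0.64), Msi1 (4.40 ± 0.39) and Olfm4 (−3.73 ± 0.69). Their median was 0.04, their mean −0.72 and the test direction down (camera adjusted p = 0.674). Apart from Notch targets, each of these lists gave the same counts adjusted over the list alone.

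**Figure D2:**
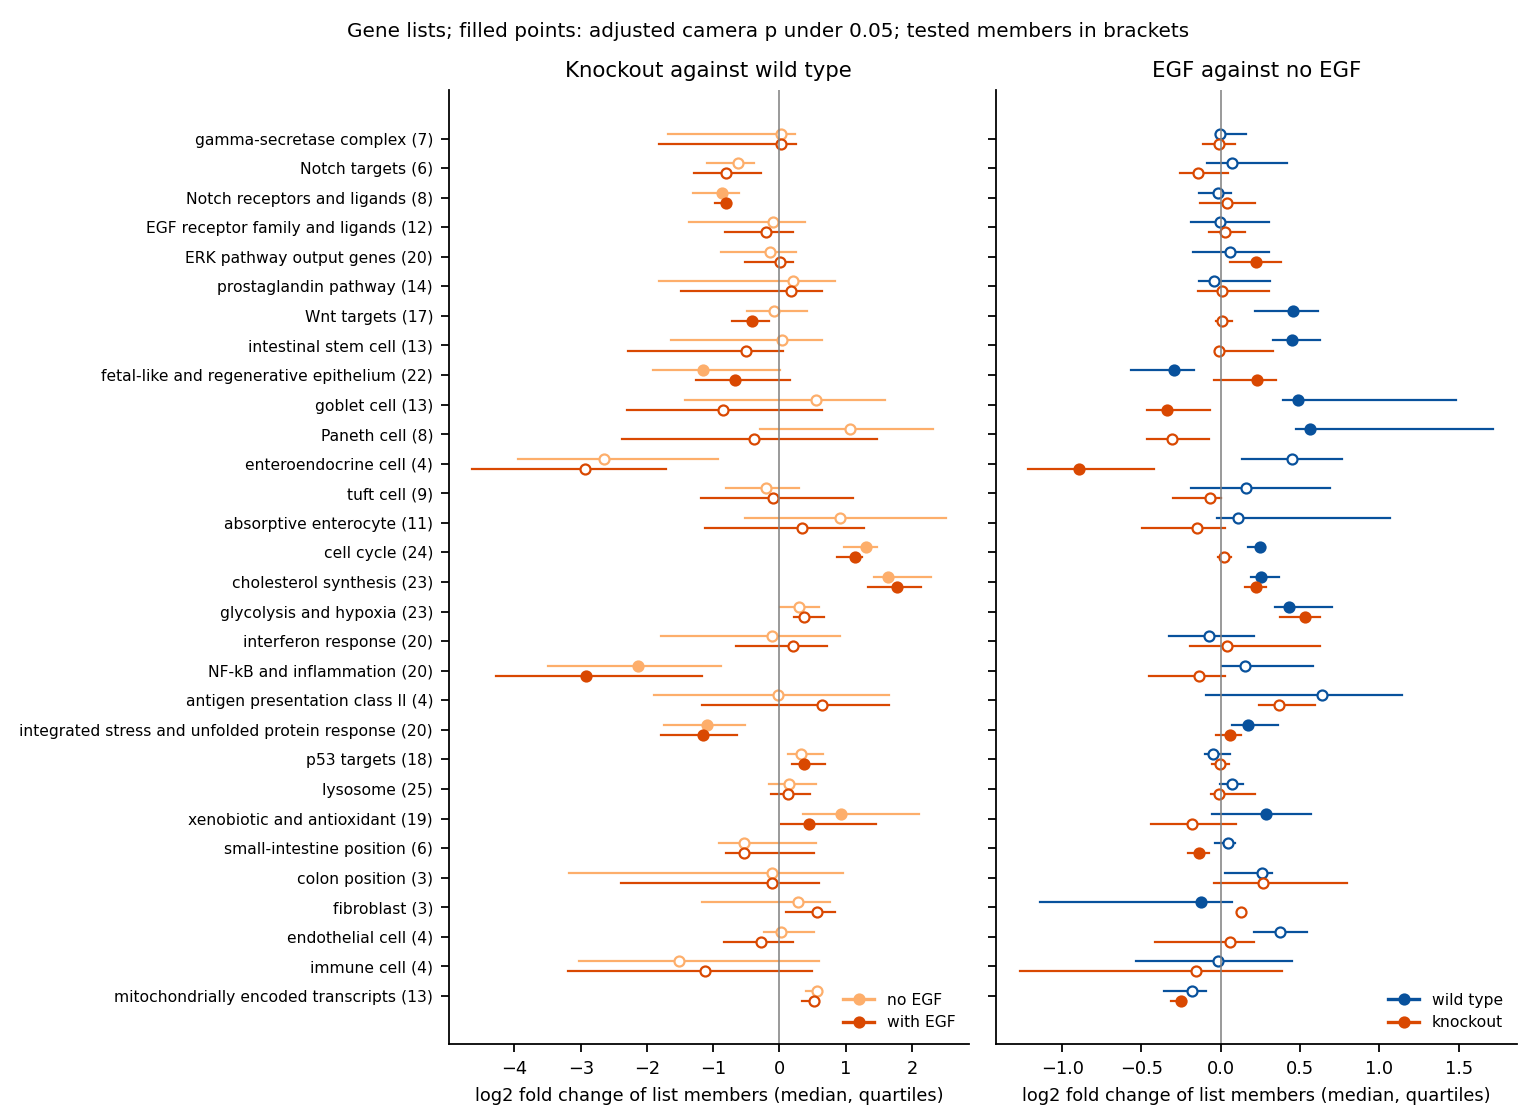
Median (points) and quartiles (lines) of the log2 fold changes of the members of each gene list, with filled points where the camera adjusted p was under 0.05. The cell cycle list has a median of 1.31 and the NF-kB list a median of −2.14 for the knockout effect without EGF.

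With EGF in the medium the knockout effect was read again in separate libraries. Bpifa6 was at least 521-fold higher in knockout, Sntb1 2400-fold (95% counting interval 663 to 19800), Slc28a2 1020-fold (282 to 8420) and Cyp2a5, a cytochrome P450 gene, 507-fold (140 to 4190). Log2 fold changes of 7.55 to 9.41 were found for Aim2 (9.41 ± 0.17), Hmga2 (9.39 ± 0.26), Slc6a15 (8.19 ± 0.21), the RNA-binding Khdrbs3 (7.88 ± 0.38), Nkx6-3 (7.66 ± 0.17), a homeobox gene of the gastric antrum, and Bend5 (7.55 ± 0.36). Lower in knockout were Tnfrsf11b (at least 5670-fold), Serpinb7 (at least 1450-fold), Lpcat2 (at least 579-fold), Ereg (at least 469-fold), Irx5 (at least 460-fold) and Timp3, an inhibitor of matrix metalloproteinases (at least 432-fold). Slco3a1 was 4560-fold lower (1260 to 37700), Serpinb11 4040-fold (1120 to 33300) and Fam111a, a protease gene, 3440-fold (952 to 28400), while Wfdc2 changed by −13.23 ± 0.20 on the log2 scale. Moves of the fold by over 1.5 times were found here without wild-type library 1 (log2 11.67 for Hmga2) or 2 (8.90 for Bend5). All wild-type counts of Sntb1, Slc28a2 and Cyp2a5 with EGF lay in library 1. Without it the group held no count, so the fitted log2 values (13.52, 12.28 and 11.29) are not measured folds. Leaving out knockout library 1 gave −12.64 for Wfdc2. The knockout counts of Wfdc2 and Serpinb11 lay in library 2 alone, those of Slco3a1 in library 1 and those of Fam111a in library 3. The fitted values without these libraries (−16.75, −14.37, −14.55 and −14.16 in that order) are thus not measured folds. The largest edgeR adjusted p among these 20 genes was 5.05e-04, for Serpinb7. In all, 9866 genes (62.4%) differed, 4928 higher and 4938 lower, with 1303 at least 2-fold higher and 1872 at least 2-fold lower. Across genes, which are not independent replicates, the log2 fold changes in both media correlated with Pearson's r = 0.908 and Spearman's rho = 0.866. Higher in both media were 4255 genes (1587.5 by chance) and lower in both 4239 (1573 by chance), and 47 were called in opposite directions.

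The groups that moved without EGF did so again with EGF. All 24 cell cycle genes were higher, led by Ccne1 (1.90 ± 0.08), Mki67 (1.77 ± 0.13), Aurkb (1.75 ± 0.15) and Ccnb2 (1.46 ± 0.15). The median was 1.14 and the camera adjusted p 4.80e-16, and adjusted p = 0.213 with an estimated correlation. Cholesterol synthesis genes were higher in 22 of 23 cases, with Acat2 (2.66 ± 0.20), Dhcr7 (2.25 ± 0.14), Insig1 (2.19 ± 0.14) and Idi1 (2.19 ± 0.16) in front and Pcsk9 lower again. By camera the list had an adjusted p of 1.04e-15, and adjusted p = 0.345 with an estimated correlation. NF-kB genes were lower in 18 of 20 cases, among them Lcn2 (−6.65 ± 0.40), Cxcl3 (−5.30 ± 0.36), Cxcl5 (−4.52 ± 0.25) and Saa3, 146-fold lower (40.1 to 1210), with Cxcl1 higher again. The adjusted p from camera was 1.55e-06, and adjusted p = 0.371 with an estimated correlation. The stress response list had 17 of 20 genes lower (Trib3 −3.70 ± 0.58, Atf5 −3.57 ± 0.43, Chac1 −3.20 ± 0.52, Ddit3 −2.24 ± 0.13) and 3 higher, Sdf2l1, Slc7a11 and Hsp90b1. Its camera adjusted p was 9.01e-05, and adjusted p = 0.371 with an estimated correlation. The fetal-like list had 15 of 22 genes lower and 6 higher, with Ereg, Trp53i11 (−5.83 ± 0.16), Ankrd1 (−4.84 ± 0.17) and Ly6a (−4.33 ± 0.08) furthest. Camera tested this list at an adjusted p of 0.00109, and adjusted p = 0.213 with an estimated correlation. Notch receptors and ligands were lower in 6 of 8 cases (Notch1 −1.44 ± 0.11, Jag1 −1.28 ± 0.08, Dll4 −0.82 ± 0.26, Dll1 −0.79 ± 0.25, the reverse of its sign without EGF). Their camera adjusted p was 0.0269, and adjusted p = 0.213 with an estimated correlation. Xenobiotic genes were lower in 3 of 19 cases, Ces1d (−2.14 ± 0.21), Cyp1b1 and Cyp3a13, and higher in 12, with Gsta2 (2.59 ± 0.16), Nqo1 (2.59 ± 0.22) and Gsta1 (2.12 ± 0.18) in front. For this list camera gave an adjusted p of 0.0269, and adjusted p = 0.405 with an estimated correlation. Wnt targets, not called without EGF, were lower in 11 of 17 cases here, with Notum (−2.30 ± 0.79), Tnfrsf19 (−2.28 ± 0.14), Lgr5 (−2.03 ± 0.09) and Sox9 (−0.98 ± 0.06) in front and Cd44 and Lgr4 higher. By camera the list had an adjusted p of 0.0269, and adjusted p = 0.379 with an estimated correlation. In the p53 list 13 of 18 genes were higher, led by the death receptor gene Fas (1.64 ± 0.09), Dcxr (1.11 ± 0.06) and the DNA repair gene Ercc5 (0.81 ± 0.06), and 3 were lower, Trp53inp1 (−1.72 ± 0.16), Perp and Polk (4 adjusted over the list alone). The p53 list had a camera adjusted p of 0.0269, and adjusted p = 0.721 with an estimated correlation. The other lists called here gave the same counts adjusted over the list alone. Without the genes of chromosomes 10 and 19 the Wnt and p53 calls ended (camera adjusted p = 0.0851 and 0.0675). The mitochondrial share was 1.03 ± 0.137% in knockout and 0.819 ± 0.139% in wild type (SD).

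Other lists of the pathway under study did not pass with EGF either. Ereg (at least 469-fold), Egf (−3.04 ± 0.40), Egfr (−0.99 ± 0.05), Errfi1 and Areg were lower in knockout and Btc (0.80 ± 0.06), Erbb3, Tgfa and Erbb2 higher among 12 genes of the receptor family (camera adjusted p = 0.208). Ptgs2 (−7.53 ± 0.23), Ptgs1 (−5.15 ± 0.18) and Ptges (−4.18 ± 0.33) were again lower and Pla2g10 (1.83 ± 0.22) higher, within 6 lower and 5 higher of 14 prostaglandin genes (median 0.18, mean −0.96, direction down, camera adjusted p = 0.12). ERK output genes split into 5 higher, Etv1 (2.61 ± 0.42), Egr1 (1.77 ± 0.15), Etv4, Etv5 and Spry1, and 5 lower, Spred3 (−1.70 ± 0.30), Epha4 (−1.09 ± 0.08), Ccnd1, Spry2 and Epha2 (camera adjusted p = 0.903). Of 6 Notch targets Dtx1 (−3.67 ± 0.86), Notch1, Nrarp (−0.81 ± 0.28) and Hes1 (−0.79 ± 0.06) were lower (camera adjusted p = 0.12). Stem cell genes were lower in 9 of 13 cases, with Msi1 (5.43 ± 0.40), Cd44 and Slc12a2 higher and Olfm4 (−5.18 ± 0.77), Smoc2 (−4.64 ± 0.36) and Igfbp4 (−4.16 ± 0.57) lowest (camera adjusted p = 0.0908). In the gamma-secretase list Aph1c (−4.06 ± 0.36), Psen1 and Ncstn (−0.43 ± 0.05) were lower and Aph1b (0.41 ± 0.16), Psen2 and Aph1a higher (median 0.03, mean −0.97, direction down). The camera adjusted p of 0.12 became 0.033 without knockout library 1 with EGF. Each of these lists gave the same counts adjusted over the list alone.

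The knockout effect differed by chromosome. Genes of chromosome 19 with a mean of at least 8 CPM were lower in knockout by a median log2 of −0.50 without EGF and −0.51 with EGF (361 genes), and genes of chromosome 10 were higher by 0.30 and 0.35 (469 genes). The medians of the other chromosomes lay between −0.10 and 0.12 without EGF and between −0.10 and 0.13 with EGF. All 14 windows of 25 neighbouring genes on chromosome 19 and all 18 on chromosome 10 lay on the side of the shift in both media. Of the genes named for the size of their change, Hmga2, Slc6a15, Timp3, Samd5, Tle2 and Mgat4c lie on chromosome 10 and Fam111a, Acta2 and Mirt1 on chromosome 19. Among other list members named, Lyz1, Lgr5, Phlda1, Ddit3, Hsp90b1, Erbb3, Gja1, Lss and Perp lie on chromosome 10 and Ankrd1, Il33, Dusp5, Fas, Habp2 and Pnliprp2 on chromosome 19. The chromosome medians of the EGF effect in either genotype stayed between −0.01 and 0.03.

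**Figure D3:**
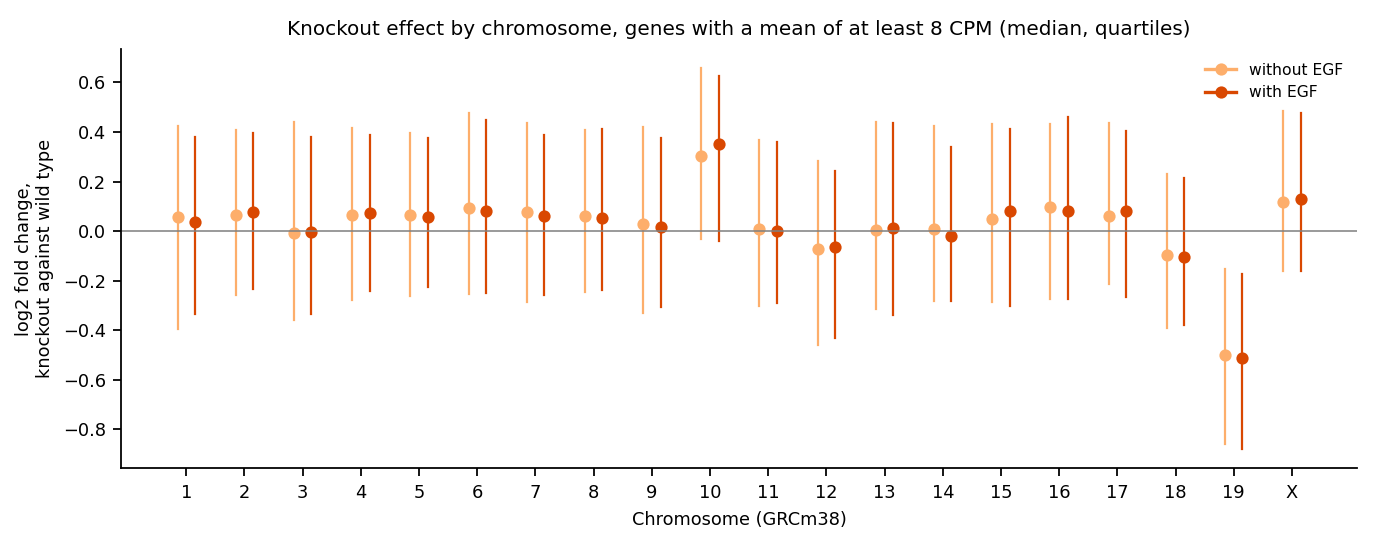
Median (points) and quartiles (lines) of the log2 knockout effect for each chromosome, without and with EGF, over genes with a mean of at least 8 CPM. Chromosome 19 lies at −0.50 and −0.51 and chromosome 10 at 0.30 and 0.35.

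The response of wild-type organoids to EGF was the next comparison. Higher with EGF were Ppp1r9a (at least 15.8-fold, from 0 counts in the 3 libraries without EGF), Hsd17b13, a lipid droplet enzyme gene (2.14 ± 0.21), the hypoxia-induced peptide gene Adm (1.76 ± 0.25) and Serpine1, the plasminogen activator inhibitor (1.74 ± 0.35). Agr2, which helps to fold secreted mucins (1.72 ± 0.14), the goblet cell peptide gene Spink4 (1.58 ± 0.32) and the hyaluronan receptor gene Lyve1 (1.68 ± 0.22) followed. So did the iron oxidase gene Heph (1.67 ± 0.42), Rragd, a GTPase gene of the mTORC1 pathway (1.65 ± 0.31), and the water channel gene Aqp5 (1.57 ± 0.22). Lower with EGF were the smooth muscle actin gene Acta2 (−2.16 ± 0.24), the glycosyltransferase gene Mgat4c (−1.76 ± 0.28) and the anion exchanger gene Slc4a9 (−1.69 ± 0.44). The cholesterol exporter gene Abcg1 (−1.23 ± 0.27), the fibronectin gene Fn1 (−1.18 ± 0.13) and Dnal1 (−1.18 ± 0.18) fell as well. Wnt7a (−1.08 ± 0.22), Mroh3 (−1.07 ± 0.23), Sptssb (−1.07 ± 0.13) and Mtus2 (−1.05 ± 0.14) were lower too. The largest edgeR adjusted p among these 20 genes was 0.0284, for Slc4a9. In all, 1976 genes (12.5%) changed, 1149 up and 827 down, with 105 at least 2-fold up and 48 at least 2-fold down. Leaving out wild-type library 3 without EGF left 1175 (687 up and 488 down) and leaving out library 1 with EGF 1222 (712 and 510). A left-out library also ended the call of Serpine1 (edgeR adjusted p = 0.0543 and 0.0636 without library 1 or 3 kept without EGF), as did a fit of only these 6 libraries (0.0834). It ended those of Heph (0.0653 to 0.0818 without library 1 or 3 of either medium) and Slc4a9 (0.0513 to 0.115 without any of the 6 but library 3 with EGF). In addition limma-voom did not call Heph (adjusted p = 0.174) or Rragd (adjusted p = 0.0725).

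Glycolysis, goblet cell, Wnt target and stem cell genes rose with EGF in wild type. Of 23 glycolysis and hypoxia genes 21 were higher, also adjusted over the list alone, led by Adm, the mitophagy receptor gene Bnip3 (1.42 ± 0.21), Ankrd37 (0.85 ± 0.16) and the carbonic anhydrase gene Car9 (0.79 ± 0.12), with a median of 0.43. The adjusted p from camera was 1.13e-26, and adjusted p = 0.0614 with an estimated correlation. Goblet cell genes were higher in 8 of 13 cases (9 adjusted over the list alone), namely Agr2, Spink4, the kallikrein gene Klk1 (1.49 ± 0.27), the transcription factor gene Spdef (0.86 ± 0.18) and 4 others. Wnt targets rose in 10 of 17 cases (12 adjusted over the list alone), with Ascl2 (0.83 ± 0.12), Tnfrsf19 (0.63 ± 0.13), the stem cell receptor gene Lgr5 (0.61 ± 0.08) and Axin2 (0.57 ± 0.06) in front. The stem cell list, which shares Ascl2, Tnfrsf19, Lgr5, Axin2 and Cd44 with the Wnt list, had 9 of 13 genes higher, also Smoc2 (1.06 ± 0.27) and Rgmb (0.74 ± 0.16). In it Cdk6 was lower (−0.32 ± 0.05), and the counts were the same adjusted over the list alone. The goblet, Wnt and stem cell calls held with an estimated correlation (camera adjusted p = 2.46e-09, 2.79e-11 and 4.78e-08, and 0.0372, 0.0372 and 0.0294 with an estimated correlation). Fetal-like genes went the other way, with 10 of 22 lower, among them Ankrd1 (−0.73 ± 0.13), Msln (−0.68 ± 0.11) and Emp1 (−0.64 ± 0.08), and Il33 higher (0.68 ± 0.10). Adjusted over the list alone 12 were lower and 2 higher. The call held with an estimated correlation (camera adjusted p = 2.37e-09, and 0.00591 with it).

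The cell cycle, stress response, xenobiotic, cholesterol and Paneth cell lists also passed as higher with EGF in wild type. Cell cycle genes were higher in 12 of 24 cases (16 adjusted over the list alone), by at most 0.34 ± 0.08 for Ccne1, then Plk1 (0.30 ± 0.07), Aurka (0.29 ± 0.08) and Tyms (0.29 ± 0.07). Stress response genes were higher in 7 of 20 (9 adjusted over the list alone), with the chaperone genes Sdf2l1 (0.61 ± 0.06) and Hspa5 (0.40 ± 0.05), the cystine transporter gene Slc7a11 (0.54 ± 0.07) and Xbp1 (0.50 ± 0.06) in front. The xenobiotic list had 7 of 19 higher (9 adjusted over the list alone), led by Ces1d (1.52 ± 0.20), Cyp1b1 (0.86 ± 0.21), Gstm3 (0.68 ± 0.18) and Hmox1 (0.64 ± 0.12). Of the cholesterol genes 5 of 23 were higher (6 adjusted over the list alone), Pcsk9 (1.00 ± 0.20), Insig1 (0.67 ± 0.14), Lss (0.41 ± 0.11), Msmo1 (0.34 ± 0.07) and Sc5d. Camera adjusted p for these lists was 3.03e-08, 3.64e-07, 6.02e-05 and 6.48e-06, and with an estimated correlation adjusted p = 0.189, 0.189, 0.189 and 0.611. Among Paneth cell genes 4 of 8 were higher, also adjusted over the list alone, namely the lysozyme gene Lyz1 (at least 6.43-fold), Pnliprp2 (1.76 ± 0.43), Itln1 (1.70 ± 0.41) and Habp2 (0.49 ± 0.11). The Paneth cell list had a camera adjusted p of 0.00561, and adjusted p = 0.0614 with an estimated correlation. Without the genes of chromosomes 10 and 19 it was not called (0.247). ERK pathway output genes were higher in 6 of 20 cases and lower in 2, Epha4 (−0.52 ± 0.08) and Spry2 (8 and 4 adjusted over the list alone). Etv5 (0.73 ± 0.08), Etv4 (0.42 ± 0.07) and Spred2 (0.32 ± 0.05) were in front, and the list did not pass (camera adjusted p = 0.293). The NF-kB list was not called either (camera adjusted p = 0.225), except without wild-type library 2 kept without EGF (0.00109), and its single called member was Saa3 (1.66 ± 0.46). Mitochondrially encoded genes took 0.819 ± 0.139% of the counts with EGF and 0.950 ± 0.112% without (SD).

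Knockout organoids were then compared with and without EGF. Serpine1 (2.00 ± 0.44) rose here too, and so did Lancl3 (2.41 ± 0.60), the Rho exchange factor gene Arhgef38 (1.63 ± 0.25), the semaphorin gene Sema7a (1.61 ± 0.39) and Samd5 (1.30 ± 0.10). Smaller rises were those of the creatine kinase gene Ckb (1.29 ± 0.21), the lipid phosphatase gene Inpp4b (1.27 ± 0.21), the microvillus myosin gene Myo7b (1.24 ± 0.24), Pcsk9 (1.22 ± 0.23) and the sialyltransferase gene St8sia6 (1.21 ± 0.13). Lower with EGF were Clca3a2 (−1.96 ± 0.25), Igfbp5, which binds insulin-like growth factors (−1.92 ± 0.22), Gsdmc2 (−1.35 ± 0.22) and the Wnt ligand gene Wnt4 (−1.23 ± 0.13). They were followed by the engulfment adapter gene Gulp1 (−1.21 ± 0.32), Cbln3 (−1.18 ± 0.29), Tmem45a (−1.12 ± 0.30), the corepressor gene Tle2 (−1.11 ± 0.22), the goblet cell peptide gene Tff3 (−1.07 ± 0.12) and Calr3 (−1.04 ± 0.20). The edgeR adjusted p of these 20 genes was at most 0.0468, for Serpine1 and Tmem45a. In all, 632 genes (4% of those tested) changed, 358 up and 274 down, with 34 at least 2-fold up and 29 at least 2-fold down. The count was 1005 to 1109 with DESeq2, limma-voom, no filter on low counts or only these 6 libraries. It fell to 396 (239 up and 157 down), 422 (243 and 179) and 371 (209 and 162) without knockout library 1, 2 or 3 kept without EGF. Without knockout library 1 or 2 with EGF it fell to 282 (168 and 114) and 296 (185 and 111). Leaving out 1 knockout library ended the calls of Serpine1 (edgeR adjusted p = 0.061 to 0.165) and Sema7a (0.0552 to 0.15) whichever of the 6 was left out. It ended those of Lancl3 (0.054 to 0.115 without library 2 or 3 kept without EGF or 1 or 2 with EGF; log2 3.38 without library 1 kept without EGF) and Pcsk9 (0.0562 to 0.0617 without library 1 of either medium or 2 with EGF). Gulp1 lost its call without any library but 3 with EGF (0.0551 to 0.166), and so did Tmem45a without any but 1 kept without EGF (0.0691 to 0.201). The same held for Cbln3 (0.0807 to 0.15 without library 3 kept without EGF or 1 or 2 with EGF) and Calr3 (0.0535 and 0.0612 without library 1 or 2 with EGF). Other settings ended the calls of Serpine1 (limma-voom 0.142, no filter 0.0582), Gulp1 (limma-voom 0.122, only these 6 libraries 0.15) and Tmem45a (limma-voom 0.0974, RLE size factors 0.0505, only these 6 libraries 0.0807).

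Glycolysis and ERK output genes led the EGF response of the knockout. Glycolysis and hypoxia genes rose in 17 of 23 cases (21 adjusted over the list alone), led by Adm (1.16 ± 0.27), Ndrg1 (0.93 ± 0.17), the glucose transporter gene Slc2a1 (0.66 ± 0.08) and Pfkfb3 (0.63 ± 0.10), with a median of 0.53. ERK pathway output genes rose in 9 of 20 cases (11 adjusted over the list alone), with the feedback inhibitor gene Spry4 (1.12 ± 0.31), the transcription factor gene Etv5 (0.64 ± 0.08), Phlda1 (0.52 ± 0.11) and the phosphatase gene Dusp5 (0.51 ± 0.10) in front. Fetal-like genes rose in 6 of 22 cases (11 up and 2 down adjusted over the list alone), with Ly6a (0.96 ± 0.09), the alarmin gene Il33 (0.84 ± 0.11), the keratin gene Krt7 (0.35 ± 0.05) and Anxa2 (0.33 ± 0.06) in front. These 3 calls held with an estimated correlation (camera adjusted p = 2.25e-45, 1.31e-10 and 1.14e-06, and 0.0263, 0.0107 and 0.0107 with an estimated correlation). The cholesterol list passed with 1 member called, Pcsk9 (2 adjusted over the list alone), and a median of 0.22. Its camera adjusted p was 1.99e-07, and adjusted p = 0.606 with an estimated correlation. The stress response list passed with Slc7a11 (0.59 ± 0.07) and Hspa5 (0.27 ± 0.05) called of 20 (3 adjusted over the list alone). Its adjusted p by camera was 0.00511, and adjusted p = 0.617 with an estimated correlation. That call ended without knockout library 2 or 3 kept without EGF (0.051 and 0.206). The goblet cell list was lower, with Tff3 and Fcgbp (−0.91 ± 0.19) called of 13, also adjusted over the list alone. Enteroendocrine genes were lower with Cpe (−0.84 ± 0.11) called of 4 (2 adjusted over the list alone). Small-intestine position genes were lower with Onecut2 (−0.21 ± 0.04) and Gata4 (−0.20 ± 0.05) called of 6 (3 adjusted over the list alone). Their camera adjusted p was 0.018, 0.00429 and 0.015, and with an estimated correlation adjusted p = 0.606, 0.0667 and 0.104. The goblet call ended without wild-type library 3 with EGF (0.115), knockout library 2 or 3 kept without EGF (0.0871 and 0.0929) or knockout library 3 with EGF (0.0859). The mitochondrially encoded list was lower as a list (median −0.25, camera adjusted p = 0.0211, and adjusted p = 0.644 with an estimated correlation). It took 1.03 ± 0.137% of counts with EGF and 1.22 ± 0.140% without (SD). Of its 13 members 0 passed by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. That call ended without knockout library 1 or 2 kept without EGF (0.0705 and 0.17) or library 2 with EGF (0.204). Among the 24 cell cycle genes 0 passed by edgeR, 1 had an unadjusted p under 0.05 and 0 passed by DESeq2 or limma-voom (camera adjusted p = 0.449). Wnt targets and stem cell genes, which rose in wild type, were not called in knockout (camera adjusted p = 0.449 and 0.469). Ephb2 was the only Wnt target that passed by edgeR, while DESeq2 and limma-voom each called 2 Wnt targets higher and 1 lower. Among stem cell genes 0 passed by edgeR, 2 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 1 each.

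The EGF effects of both genotypes were then set against each other. Across genes, which are not independent replicates, their log2 fold changes correlated with Pearson's r = 0.0951 (jackknife SE over libraries 0.0367) and Spearman's rho = 0.126. Leaving out each library in turn gave r of 0.0445 to 0.0861, all below the value of the full set. In all, 112 genes rose in both genotypes (26 by chance), 70 fell in both (14.3 by chance) and 73 were called in opposite directions. The interaction, the EGF effect in knockout minus that in wild type, passed for 856 genes (5.4%), 399 positive and 457 negative, by edgeR's quasi-likelihood test. The balance of directions depended on the setting, with 434 positive and 396 negative by RLE size factors and 469 and 780 without wild-type library 2 kept without EGF. Without wild-type library 3 kept without EGF 567 were left (277 and 290), without wild-type library 1 with EGF 561 (265 and 296) and without knockout library 2 with EGF 591 (297 and 294). DESeq2 gave 628 and 625, limma-voom 521 and 735 and no filter 556 and 713. The most positive were Lancl3 (3.27 ± 0.62), Fn1 (2.36 ± 0.31), the long noncoding RNA gene Mirt1 (2.36 ± 0.58), the BMP antagonist gene Nbl1 (2.33 ± 0.46) and Acta2 (2.26 ± 0.35). All of these stood higher without than with EGF in wild type and below 2 CPM in knockout. Acta2, for example, fell from 8.40 ± 1.11 to 1.88 ± 0.448 CPM with EGF in wild type and stood at 1.36 ± 0.528 and 1.48 ± 0.241 CPM in knockout. The most negative were Ppp1r9a and the collagen receptor gene Ddr2, given without a fold because a group had at most 3 counts (edgeR adjusted p = 2.02e-04 and 0.036). Next came the NADPH oxidase gene Nox1 (−3.07 ± 0.62), the carboxylesterase gene Ces1d (−2.40 ± 0.30) and the chemokine gene Ccl9 (−2.36 ± 0.42). Nox1 stood at 2.83 ± 1.91 CPM without and 7.96 ± 2.38 CPM with EGF in wild type and at 4.09 ± 1.28 without and 1.36 ± 0.139 CPM with EGF in knockout. Leaving out 1 library ended the calls of Mirt1 (edgeR adjusted p = 0.0527 to 0.0874 without wild-type library 3 kept without EGF or 1 or 3 with EGF, or without knockout library 1 or 3 kept without EGF or 1 or 2 with EGF). The call of Ddr2 ended too (0.061 to 0.177 without library 1 of wild type with EGF or of knockout in either medium, or knockout library 3 with EGF; 0.116 with limma-voom), as did that of Nox1 (0.0549 to 0.0599 without wild-type library 3 kept without EGF or any knockout library with EGF). The interaction moved by over 1.5-fold for Lancl3 (4.24 without knockout library 1 kept without EGF), Mirt1 (3.17 without knockout library 2 kept without EGF and 1.68 without library 1 with EGF) and Nox1 (−3.76 without wild-type library 2 kept without EGF).

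Fetal-like and goblet cell genes responded to EGF differently in the genotypes. The interaction was positive for 8 of 22 fetal-like genes (12 adjusted over the list alone), led by Sprr1a (1.10 ± 0.24), Ly6a (1.09 ± 0.11), Ankrd1 (1.08 ± 0.26) and Emp1 (0.97 ± 0.11). It was negative for 6 of 13 goblet cell genes (10 adjusted over the list alone), led by Spink4 (−2.28 ± 0.49), Klk1 (−1.83 ± 0.36), Tff3 (−1.49 ± 0.17) and Agr2 (−1.33 ± 0.19). The list medians were 0.51 and −0.92, and both calls held with an estimated correlation (camera adjusted p = 2.47e-17 and 1.84e-12, and 5.25e-04 and 0.0328 with an estimated correlation). Wnt targets were negative in 5 of 17 cases (7 adjusted over the list alone), with Ascl2 (−1.02 ± 0.17), Lgr5 (−0.64 ± 0.12), Axin2 (−0.58 ± 0.08) and Sox9 (−0.49 ± 0.08) in front. So were stem cell genes in 5 of 13 cases (6 adjusted over the list alone), also Rgmb (−1.08 ± 0.22) and Slc12a2, with Cdk6 positive (0.34 ± 0.07). Negative were also Cyp2b10 (−1.23 ± 0.22), Ces1d and Gsta3 of 19 xenobiotic genes (7 adjusted over the list alone) and Pnliprp2 (−2.54 ± 0.63) and Habp2 (−0.81 ± 0.15) of 8 Paneth cell genes (4, and 1 positive, adjusted over the list alone). Camera adjusted p for these 4 lists was 2.06e-06, 2.49e-04, 2.87e-05 and 0.00276, and with an estimated correlation adjusted p = 0.104, 0.0932, 0.149 and 0.0772. The ERK list was positive, with 5 of 20 genes called, also adjusted over the list alone, namely Dusp5 (0.68 ± 0.14), Phlda1 (0.64 ± 0.15), Epha4 (0.58 ± 0.12), Spry2 (0.42 ± 0.10) and Epha2. Camera tested this list at an adjusted p of 0.00289, and adjusted p = 0.143 with an estimated correlation. The cell cycle list was negative (median −0.20, camera adjusted p = 6.25e-05, and adjusted p = 0.412 with an estimated correlation). Of its 24 members 0 passed by edgeR, 12 had an unadjusted p under 0.05, 0 passed by DESeq2 and 7 by limma-voom. The NF-kB list was negative with Saa3 called of 20, also adjusted over the list alone (median −0.34). Camera gave it an adjusted p of 0.0204, and adjusted p = 0.63 with an estimated correlation. This call ended without wild-type library 1 kept without EGF (0.192) or 3 with EGF (0.163) or knockout library 1 kept without EGF (0.0705) or 3 with EGF (0.0535). The glycolysis list, which rose in both genotypes, had 1 member with an interaction, Pfkfb3 (0.64 ± 0.13; camera adjusted p = 0.91). Without the genes of chromosomes 10 and 19 the ERK and Paneth calls of the interaction ended (camera adjusted p = 0.152 and 0.604).

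**Figure D4:**
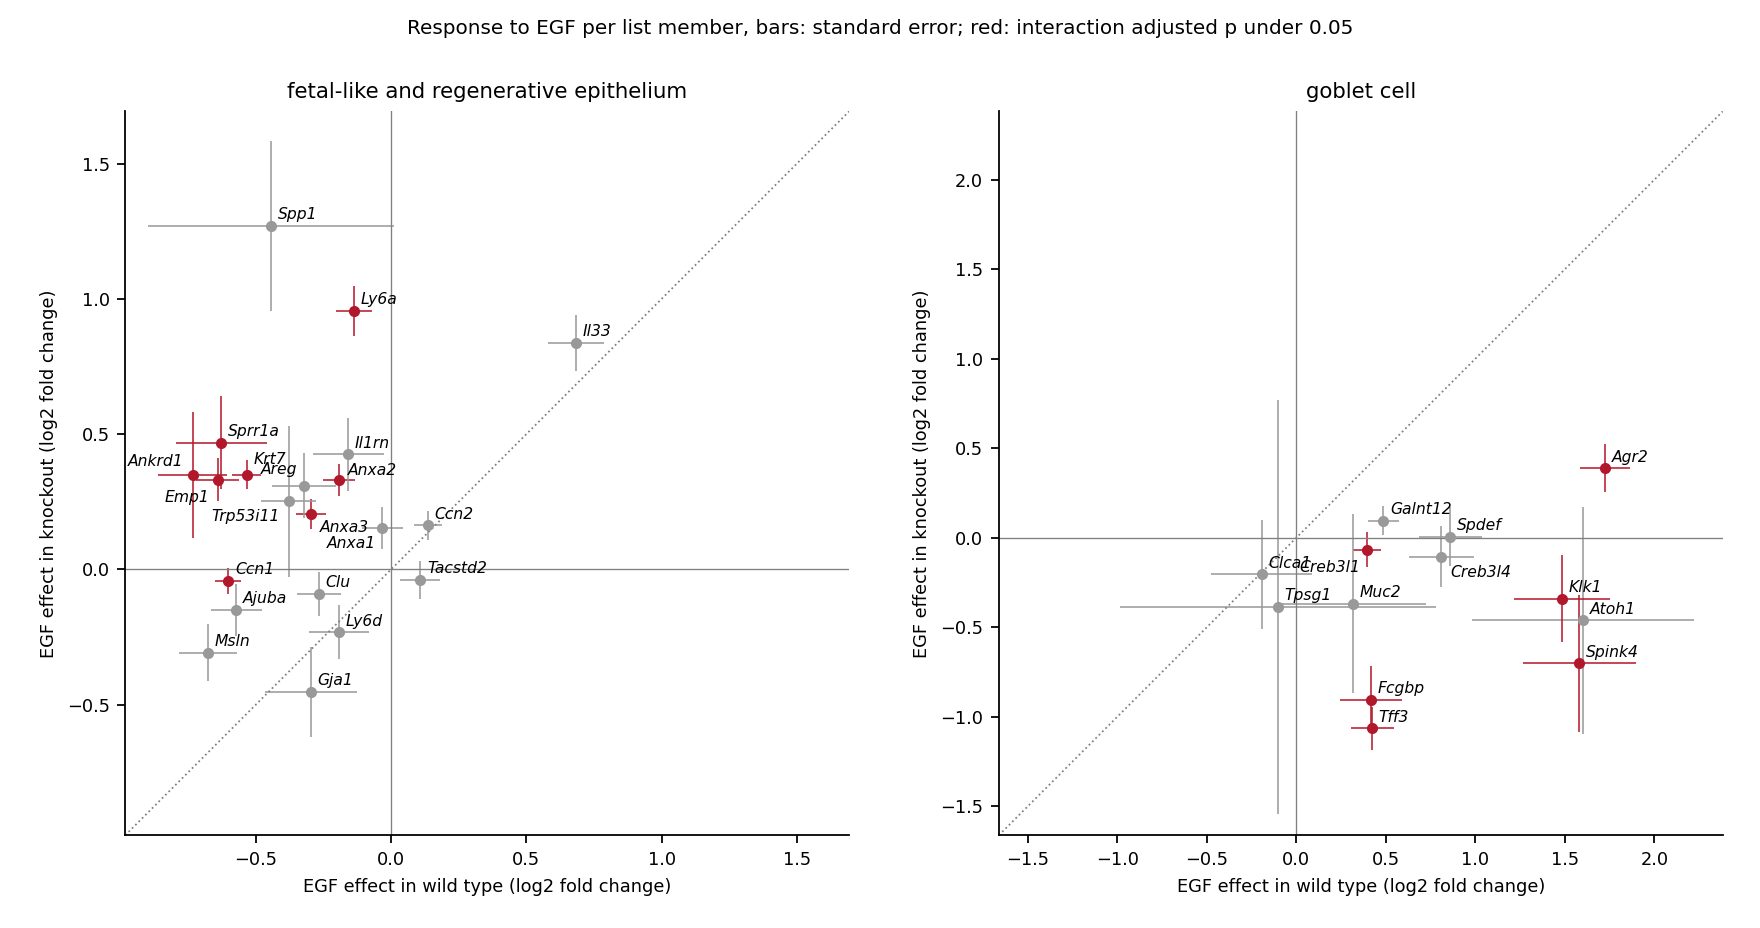
Log2 fold change with EGF in wild type (horizontal axis) and in knockout (vertical axis) for the members of the fetal-like and goblet cell lists, with SE as bars and genes with an interaction in red. List medians over all tested members are −0.30 in wild type and 0.23 in knockout for fetal-like genes and 0.49 and −0.34 for goblet cell genes.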

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

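The gene counts and list tests of the interaction were set before the data were examined, whereas the tests of normalization for both patterns, of chromosomes 10 and 19 and of organoid lines and of other epithelium for the first pattern were chosen only after the result was seen. Each result in the next paragraph stands here because its interaction passed the test.

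The interaction passed for 856 genes. Among lists, the median interaction was 0.51 for fetal-like genes, 0.12 for ERK output and 0.29 (0.295) for fibroblast genes, where Acta2 was the only member called (camera adjusted p = 0.0491, and adjusted p = 0.248 with an estimated correlation). It was −0.92 for goblet cells, −0.98 for Paneth cells, −0.43 for stem cells, −0.34 for NF-kB, −0.31 for Wnt targets, −0.28 for xenobiotic genes and −0.20 for the cell cycle. With an estimated correlation the fetal-like and goblet calls held (camera adjusted p = 5.25e-04 and 0.0328). Lost were those of ERK output (0.143), Paneth cells (0.0772), stem cells (0.0932), NF-kB (0.63), Wnt targets (0.104), xenobiotic genes (0.149) and the cell cycle (0.412). The fibroblast call ended without library 2 of any of the 4 groups (0.358 and 0.0865 for wild type without and with EGF, 0.0696 and 0.0505 for knockout) and without knockout library 3 with EGF (0.058). It also ended with RLE size factors (0.0544), with a replicate block (0.063) and without the genes of chromosomes 10 and 19 (0.991). Among genes named for an EGF effect in wild type, the interaction (log2) was 0.45 for Egfr, −2.29 for Hsd17b13, −1.33 for Agr2, −1.36 for Lyve1, −2.21 for Rragd and −2.28 for Spink4. It was 2.26 for Acta2, 1.65 for Mgat4c, 2.36 for Fn1 and 1.00 for Mtus2. For Ppp1r9a it is given as the edgeR adjusted p alone, 2.02e-04. Among genes named for an EGF effect in knockout it was 3.27 for Lancl3, 1.69 for Samd5, 1.15 for Inpp4b, −1.39 for Clca3a2, −1.62 for Igfbp5, −0.92 for Wnt4, −1.27 for Tmem45a and −1.49 for Tff3. Genes named for the interaction alone were Mirt1 (2.36), Nbl1 (2.33), Nox1 (−3.07), Ces1d (−2.40), Ccl9 (−2.36) and Ddr2 (edgeR adjusted p = 0.036).

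Most genes tested differed between knockout and wild type, and without EGF 31 genes were found in knockout only and 64 in wild type only. Such genes were called, had a mean of at least 1 CPM in that genotype and at most 3 counts over the group of the other. An error of scaling adds 1 constant to the log2 fold changes of all genes. It is argued against as the cause because, with any of 41 constants from −2 to 2 applied to the knockout libraries without EGF, at least 10135 genes were called, at the constants 0 and 0.1. Fibroblasts, endothelial and immune cells are argued against because the median level of their lists reached at most 0.0676 CPM in any group. The genes found in 1 genotype only had a median of 2.57 CPM, but their definition asks for at least 1 CPM, so this contrast was partly set in advance. The highest members of the cell type lists lay above that median, namely Esam (40.2 CPM in knockout with EGF), Fbln1 (11.9 CPM) and Cd68 (3.60 CPM in wild type with EGF). Chromosomes 10 and 19 are not the whole cause, since 90.6% of the calls lie on other chromosomes. Epithelium of another gut segment or of the stomach in part of the cultures stays open, since the stomach genes not seen before did not pass in either direction with an estimated correlation (larger camera p = 0.179 of the 2 media). What also stays open is a difference between tumours or organoid lines, which cannot be told apart from the loss of Psen1, because the labels name a line or animal for 0 libraries and replicates differ by a biological coefficient of variation of only 7.4%.

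The fetal-like list responded to EGF upward in knockout and downward in wild type, while the goblet cell list rose in wild type. In knockout the goblet cell list was lower with only 2 of 13 members called (camera adjusted p = 0.018, and adjusted p = 0.606 with an estimated correlation). That call ended in some fits that leave out 1 library (0.0859 to 0.115), so the pattern weighed here is the interaction alone. A single library as its cause is argued against by the fits that leave out 1 library, where the largest camera adjusted p for either list was 1.43e-10. Normalization would move both lists by the same constant. It is argued against because their median interactions lay 1.43 (1.429) apart, a distance that no such constant changes. The Wilcoxon shift was 1.51 (95% interval 1.09 to 2.01), where the interval runs over genes, which are not independent replicates. The lists were set against each other after their opposite interactions were seen, so an interval without 0 adds no support. Genes near the detection limit in all groups are argued against by members with a mean of at least 8 CPM over all libraries. By camera with the preset correlation these gave a p of 2.99e-17 or less. Their median interaction was 0.52 for 21 fetal-like genes and −1.32 for 9 goblet cell genes. A member can reach that mean through 1 genotype alone, so genes low only in the other genotype stay open. A difference between organoid lines that goes with genotype cannot be told apart here either, for the same reason (7.4%), and a biological difference by Psen1 stays open as untested.

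Genes of chromosome 19 were lower and those of chromosome 10 higher in the knockout. GC content or gene length is argued against because genes of other chromosomes matched for both had medians of 0.08 (0.077) and 0.05 (0.052), at most 0.171 of the shift. A few genes or 1 region are argued against for chromosome 19, where 100% of the windows lay below 0 without EGF, with values of −0.75 to −0.328. On chromosome 10 100% of the windows lay above 0, but with values of 0.057 to 0.512. The lowest lay within the medians of the other chromosomes without EGF (−0.097 to 0.119), so a shift of only part of chromosome 10 stays open. A different number of copies of either chromosome predicted windows on the side of the shift along its whole length in both media. For both chromosomes 100% of the windows met this, a count that does not ask how far a window lay from 0. As a hypothesis, the knockout cultures may thus carry fewer copies of chromosome 19 in at least part of the cells. They may likewise carry more copies of all or part of chromosome 10. The deposited table holds no DNA data.

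Other splits of the same libraries into groups of 3 gave fewer calls in every comparison of 2 groups. For the knockout effect without EGF, the knockout effect with EGF and the EGF effect in knockout, 1 of 10 splits, the real one, called as many genes and the highest other split called 0. For the EGF effect in wild type it was 1 of 10 with a highest other of 15. With 10 splits a share under 0.05 cannot be reached. For the interaction 4 of 100 splits called as many genes, the real one included, and the highest other called 4787. All 3 larger counts came from the 9 splits that put the genotypes furthest out of balance. The lowest count among these 9 was 0, so such imbalance did not always give many calls, and the cause was not tested. The 44 splits that kept the genotypes in balance called at most 856, the real split. Every other split of these 44 put knockout and wild-type libraries into the same group, which widens the spread within groups. Few calls were thus bound to follow. The other splits in the comparisons of 2 groups mix the 2 conditions in the same way, so these counts cannot decide on chance.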

How the results depend on the processing

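The alternatives were set before the data were examined, except that list tests with RLE size factors, without the genes of chromosomes 10 and 19, or without 1 library were chosen only after the result was seen. Both knockout counts kept within 1.5 times under every setting (9538 to 10474 genes without EGF and 9349 to 10180 with EGF), and RLE size factors left the balance of higher and lower genes at 4868 and 5251 without EGF. The EGF count in knockout (632) was 1031 with DESeq2, 1109 with limma-voom, 1005 with no filter, 1105 with only the 6 libraries compared and 282 to 602 when each library was left out. The count in wild type (1976) was 1175 to 2274 without 1 library and 1484 to 2513 under other settings, and the interaction (856) was 561 to 1249 without 1 library and 830 to 1269 under the other settings except the block. The list calls (46 of 150) fell to 10 with an estimated correlation and rose to 84 with fry, which asks whether members change at all and not whether they change more than other genes. They were 44 to 49 without 1 library, 44 with RLE size factors and 42 without the genes of chromosomes 10 and 19. The agreement across genes was 0.5117 with no filter for the knockout effect and 0.0208 for the EGF effect, where genes with almost no counts enter, and 0.9081 and 0.0952 with RLE size factors. Of 1289 alternative fits of the 103 named results that were called, 1216 kept the call, 73 lost it in the same direction (60 of them by leaving out 1 library, 6 with limma-voom) and 0 reversed. The 163 fits of the 12 named results without a call gave 0 calls. Without 1 library the left group rests on 2, whose spread is pooled with the other groups. For changes other than those named as such, the cause was not tested. Replicate numbers did not pair the libraries: deviations of 18 same-number pairs correlated between −0.24 and 0.152, and 5 of 12 libraries correlated best with their own number. With the number as a block the counts were 10031, 9756, 1807, 553 and 787 genes and 45 lists. That block ended the named calls of Serpine1 (edgeR adjusted p = 0.11) and Tmem45a (0.0762) for EGF in knockout. It also ended the fibroblast calls for EGF in wild type (camera adjusted p = 0.0721) and the interaction (0.063), and added the stress response list in the interaction (0.0439).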

Other observations

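The stomach test was chosen only after the result was seen, and so were the stomach genes, Apc and the imprinted genes named below. Some genes known from the stomach stood out among those higher in the knockout. Muc6, a mucin of gastric glands, rose from 1.52 to 301 CPM without EGF and the pepsinogen gene Pgc from 4.76 to 478 CPM. Likewise, the gastrokine genes Gkn1 and Gkn2 went from 14.4 to 241 and from 0.619 to 28.8 CPM, and the antral homeobox gene Nkx6-3 went from 0.158 to 37.9 CPM. Cldn18, a stomach claudin, went from 464 to 2210 CPM, Vsig2 from 36.9 to 258 and Psca from 35.4 to 165, whereas the trefoil peptide gene Tff2 went down from 237 to 22.8 CPM and Aqp5 from 7.95 to 0.0863 CPM. A stomach-like expression pattern was tested on the 13 list members not seen before: 8 were higher and 2 lower in either medium, with a camera p of 0.00367 without EGF and 0.00338 with EGF (0.178 and 0.179 with an estimated correlation). The lower genes were Tff1 and Tff2 without EGF and Tff2 and Capn8 with EGF. The preset correlation thus fits such a pattern, as a hypothesis, while the estimated correlation leaves it open.

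Position genes of the gut moved in both directions, and neither position list passed without EGF (camera adjusted p = 0.674 for the small intestine and 0.773 for the colon). Hoxa13, a homeobox gene of the hindgut (chromosome 6, 52257694 to 52260880, GRCm38), was lower in knockout by a log2 fold change of −6.23 ± 0.48 without EGF and −4.69 ± 0.41 with EGF. Gata4, a factor of the proximal gut (chromosome 14, 63198922 to 63271692), was higher by 1.55 ± 0.05 and 1.25 ± 0.05, while 4 of the 6 tested small-intestine genes were lower. Apc, the tumour suppressor gene mutated in these mice (chromosome 18, 34220924 to 34322552), stood at 102 ± 0.913 and 94.2 ± 4.14 CPM in wild type and at 267 ± 7.83 and 276 ± 9.10 CPM in knockout without and with EGF. Its log2 fold changes were 1.39 ± 0.05 and 1.55 ± 0.05 (edgeR adjusted p = 3.68e-16 and 9.49e-17). Snrpn, an imprinted gene (chromosome 7, 59982495 to 60140219), had 441 counts in the 3 wild-type libraries without EGF and 0 in knockout; its level is uncertain where other transcripts overlap it. Other imprinted genes went either way without EGF. Kcnq1ot1 was higher in knockout (3.38 ± 0.25), as were Impact (0.77 ± 0.15), Plagl1 (0.41 ± 0.11, on chromosome 10) and Igf2r (0.18 ± 0.05). Zrsr1 (−0.77 ± 0.14) and Cdkn1c (−0.51 ± 0.19) were lower, while Mest, Nnat, Phlda2 and Rasgrf1 did not pass.

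Lists of secretory and absorptive cells did not pass the test for the knockout effect without EGF. Goblet cell genes split into 6 higher, among them Agr2 (2.44 ± 0.14), Klk1 (1.94 ± 0.27) and Galnt12 (1.92 ± 0.09), and 5 lower, led by Creb3l1 (−2.82 ± 0.09; camera adjusted p = 0.674). With EGF 4 were higher and 7 lower (camera adjusted p = 0.281). Of 8 Paneth cell genes 4 were higher, Lyz1 (at least 21.4-fold), Defa30 (2.38 ± 0.95), Habp2 and Itln1, and Nupr1 (−4.56 ± 0.25) and Mmp7 (−2.93 ± 0.32) lower (camera adjusted p = 0.815). Enteroendocrine genes were lower in 3 of 4 cases, Chgb (25.7-fold, 95% counting interval 6.74 to 218), Insm1 (−3.77 ± 0.47) and Cpe (−1.52 ± 0.10; camera adjusted p = 0.26). With EGF the camera adjusted p was 0.0654. It was 0.0473 without knockout library 3 kept without EGF, 0.0496 without wild-type library 3 with EGF and 0.0408 without the genes of chromosomes 10 and 19. Tuft cell genes had Siglecf (5.09 ± 0.66) and Ltc4s (2.03 ± 0.44) higher and Alox5 (at least 5.47-fold), Dclk1 (−3.79 ± 0.37) and Trpm5 lower of 9 (camera adjusted p = 0.914). Of 11 enterocyte genes 6 were higher, Alpi 40.9-fold (11 to 343), and Rbp2 (33.9-fold, 9.01 to 285) and Apob (−4.27 ± 0.12) lower (camera adjusted p = 0.914). These counts were the same adjusted over the list alone.

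Stress, immune and metabolic lists also gave values in both directions without EGF. Glycolysis and hypoxia genes were higher in 16 of 23 cases and lower in 4, Car9 (−5.05 ± 0.17), Vegfa (−2.07 ± 0.20), Pfkfb3 (−1.78 ± 0.09) and Adm (camera adjusted p = 0.503). Interferon genes were higher in 7 of 20 cases and lower in 6, with Zbp1 (at least 15.1-fold), Oas2 (28.7-fold, 7.59 to 243), Ifit3 (−4.43 ± 0.72) and Isg15 (−2.81 ± 0.75) lowest (median −0.11, mean −0.76, test direction up, camera adjusted p = 0.878). Of 4 class II genes H2-Eb1 (3.86 ± 0.34) was higher and Cd74 (−4.66 ± 0.57) and H2-DMa (−0.96 ± 0.40) lower (median −0.02, mean −0.21, test direction up, camera adjusted p = 0.914). The p53 list had 11 of 18 genes higher, led by Fas (2.14 ± 0.10), Dcxr (1.55 ± 0.06) and Eda2r (0.86 ± 0.11), and 3 lower, Trp53inp1 (−1.80 ± 0.16), Perp and Polk (camera adjusted p = 0.0542). That test passed without wild-type library 1 or 3 kept without EGF (0.0153 and 0.0427) or 1 with EGF (0.0477), and without knockout library 2 or 3 kept without EGF (0.0368 and 0.047) or 1, 2 or 3 with EGF (0.0482, 0.0481 and 0.0409). Lysosome genes were higher in 11 of 25 cases (12 adjusted over the list alone) and lower in 7, with Sqstm1 (−1.68 ± 0.10), Psap (1.20 ± 0.05), Gusb (1.12 ± 0.11) and Ctsz (−0.89 ± 0.06) furthest (camera adjusted p = 0.603).

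Position and non-epithelial lists held few tested members. Small-intestine position genes had Gata4 and Pdx1 (0.88 ± 0.10) higher and Slc10a2 (−2.38 ± 0.13), Onecut2 (−1.01 ± 0.04), Bcl11b and Gata5 lower of 6 (camera adjusted p = 0.674). Among colon position genes Mettl7b (2.03 ± 0.29) was higher and Hoxa13 lower of 3 (camera adjusted p = 0.773). Of 3 fibroblast genes Fbln1 (1.25 ± 0.29) was higher and Acta2 (−2.61 ± 0.25) lower (median 0.27, mean −0.36, direction down, camera adjusted p = 0.801). Of 4 endothelial genes Esam (1.61 ± 0.09) was higher (camera adjusted p = 0.503). Of 4 immune genes Ptprc (2.78 ± 0.78) was higher and Itgam (−3.40 ± 1.01) and Csf1r (−2.91 ± 0.56) lower (camera adjusted p = 0.815). The fibroblast list was lower with EGF in wild type through Acta2, of 3 tested (camera adjusted p = 0.0489, and adjusted p = 0.189 with an estimated correlation). This call ended with RLE size factors (0.0515) and without wild-type library 2 kept without EGF (0.423) or 1 or 2 with EGF (0.0539 and 0.0863). Without the genes of chromosomes 10 and 19, Acta2 among them, it turned up (0.857). The mitochondrially encoded list was not called with EGF in wild type (camera adjusted p = 0.131), but passed as lower without wild-type library 1 kept without EGF (0.00836) or library 2 with EGF (0.00317). With EGF in knockout the NF-kB list was not called (camera adjusted p = 0.0886), but passed as lower without knockout library 3 kept without EGF (0.00432), without library 2 with EGF (0.0333) and without the genes of chromosomes 10 and 19 (0.0445). Its called member Saa3 was 13.6-fold lower (3.4 to 118). The stress response list of the interaction, with Sdf2l1 (−0.59 ± 0.08) and Xbp1 (−0.55 ± 0.08) negative (camera adjusted p = 0.0519), passed without wild-type library 1 kept without EGF (0.0295) or 3 with EGF (0.00587). It also passed without knockout library 2 or 3 kept without EGF (0.0244 and 0.00137) or 1 with EGF (0.018), and without the genes of chromosomes 10 and 19 (0.0475).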
